A study of Caenorhabditis elegans with 83 samples.

How the data were processed

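Small RNAs of whole day 1 adult Caenorhabditis elegans were sequenced in 83 libraries, which form 28 groups by background, genotype, generation and treatment. Every group held 3 libraries except the wild-type SX1263 group fed anti-GFP bacteria at P0, which held 2. SX1263, a strain with a germline GFP reporter, gave 59 libraries, and EG6089, a second GFP reporter strain, gave 24. Per the labels, animals grew at 20 degrees, RNA was taken with TRIZOL, and libraries were made with small RNA kits. P0 animals ate bacteria with dsRNA against GFP or with the empty vector, and their descendants ate ordinary bacteria, so that P0 and F3 also differed in food.

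The deposited files held raw counts per gene from HTSeq, 1 file per library. The submitters' processing notes name cutadapt, FastQC, Bowtie2, HTSeq and DESeq2 without versions, and the builds WBcel235 and ce11. They give neither the strand used in counting nor a length filter. Whether the counts hold sense or antisense small RNAs, or both, is therefore unknown. Genes that overlap, or that have close copies such as F-box, msp and histone genes, carry that uncertainty. The 5 HTSeq counter rows, which held 50.8 to 62.0% of all records in SX1263 and 29.2 to 42.4% in EG6089, were left out. These shares differ between the sets, so whether both were counted alike is not known. SX1263 files held 20449 gene rows and EG6089 files 20390. Of these, 20159 and 19902 were matched by gene identifier or sequence name to the Ensembl annotation of WBcel235, and the 288 and 487 unmatched rows, with 0.572% and 0.792% of counts, were kept. A genome sequence was not used here. Both sets had a row for GFP, and SX1263 had a row for CB-unc-119, read from its name alone as the C. briggsae unc-119 gene, a common transgenesis marker. The labels do not say whether it lies on the GFP transgene.

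Genes were tested with edgeR 4.0.16 under R 4.3.3, by the robust quasi-likelihood F test on counts scaled by TMM factors. The low-count filter filterByExpr used groups, a minimum count of 10 and a minimum total of 15. All groups of a background and generation were fitted together, or all of a background for comparisons between generations. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are counts per 1000000 (CPM) scaled by the same factors, as mean and SD, and changes are on the log2 scale with their SE. All tests were two-sided except the relabelling tests of neighbouring genes, which were one-sided. There were 14 comparisons of anti-GFP against control, 9 of a mutant against wild type, 2 of met-2 against set-25 and 3 between generations, besides 6 tests of whether an effect differed between genotypes or generations. Differences in effect on the GFP and CB-unc-119 rows were also tested pair by pair, and adjusted over families of 19 and 15 tests. A fold against a group with no counts was computed against a floor of 3 counts over the group and is given as a lower bound. Each library's own floor of 3 counts came to 0.165 to 0.837 CPM in SX1263 and 0.492 to 1.41 CPM in EG6089. Floors cover counting error only, since the reads carry no molecular identifiers.

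The choices so far, the lists below and the alternatives were fixed before the data were examined, except the pairwise tests and the tests of neighbouring genes. The 30 lists covered the small RNA pathway, chromatin regulators, endogenous genes with sequence in the reporters, H2B genes, histone genes, oogenesis, spermatogenesis, ERGO-1 targets, WAGO targets, body muscle, intestine, neurons, collagens, zygotic embryo genes, heat shock genes, ribosomal proteins, the F-box, MATH-BATH and pals families, C-type lectins, chemoreceptors, nuclear hormone receptors, pseudogenes, X-chromosome genes and autosome arms (the outer 25% of each autosome at either end). The lists of microRNAs, miR-35, 21U-RNA genes, ribosomal RNA genes and transposon genes had no rows under the names searched, and H2B genes had under 5 tested members, which left 24. They were written from memory of the field, not from these samples. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation.

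Named genes followed a rule. It took met-2, set-25, the reporter rows and the reporter list. It took up to 10 genes each way for each mutant at F3 and for met-2 at F15, by size of change, among called genes with at least 5 CPM in the higher group and no overlap between groups. Other comparisons gave 3 each way, each list up to 4 called members or the 2 most abundant ones, each overlap up to 5 genes, and each test of differing effects up to 6. Chance gives 10% of comparisons of 3 against 3 libraries without overlap. The CB-unc-119 row in some comparisons and the genes of a region on chromosome II were chosen after their values were seen.

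Alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0, a replicate term, protein-coding genes and pseudogenes only, a fit to the compared groups only, control and treated libraries together, and leaving out each library. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups. The fit was tested on simulated data with 200 changed genes. For met-2 at F3 in SX1263 it recovered 79.6% of genes raised 4-fold and 75.5% of those lowered 4-fold, and 38.8 and 46.8% at 2-fold. For the EG6089 mutant at F3 it recovered 98.0 and 83.7% at 4-fold. For treatment of wild type at P0 in SX1263 it recovered 78 and 65.3% at 4-fold, and 28 and 22.9% at 2-fold. Simulated counts were drawn independently, without any structure by replicate number. The real comparisons of these mutants with wild type also called many more than 200 genes. Recovery in the real data can therefore differ from these shares. Among 82 pairs of replicates none were identical, and the chi-square per degree of freedom ran from 2.62 to 129. In SX1263 at P0, pairs with replicate 1 gave the highest values in every group that held all 3 replicates. In wild-type controls they gave 88.2 and 83.8, against 8.67 for replicates 2 and 3. The main fits had no replicate term and shared 1 estimate of spread among all groups of a fit. At F3 in SX1263 the chi-square of control pairs ran from 5.63 to 9.24 in wild type and from 20.1 to 59.1 in met-2;set-25. Tests may therefore be too strict for groups that vary less and too lax for groups that vary more. Nothing in the labels says that replicates came from separate cultures, so each p measures the spread between these samples.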

Results

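Small RNA reads per gene were compared between wild-type animals and mutants in met-2 and set-25, the genes of histone H3 lysine 9 methyltransferases, in lines that carry a germline GFP reporter. The series title places the study in the role of this methylation in the inheritance of small RNAs across generations. In SX1263, wild type, met-2(n4256), set-25(n5021) and the met-2;set-25 mutant were sampled at P0, the generation fed dsRNA against GFP, and at F3, and wild type and met-2 also at F15. In EG6089, wild type and met-2;set-25 were sampled at P0 and F3. Gene counts per library had a median of 7469120 in SX1263 and 3660163 in EG6089. By generation they ran from 3691980 to 18225929 at P0, 3583283 to 11214443 at F3 and 4459423 to 10218837 at F15 in SX1263, and from 2134929 to 6102965 at P0 and 2638623 to 5878299 at F3 in EG6089. The 10 most abundant genes took 5.32 to 9.14% of gene counts in SX1263 and 5.98 to 12.1% in EG6089. Values are means and SD of n = 3 libraries unless stated, and positions are on WBcel235.

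Small RNAs of met-2 were lower in its mutants, and those of set-25 were lower in mutants of either gene, though not every fall was called. The met-2 gene (chromosome III, 8375300 to 8380848) had 322 ± 27.2 CPM in wild-type controls at P0 and 93.0 ± 12.4 CPM in met-2 mutants, 3.46-fold lower (log2 change -1.79, SE 0.18, adjusted p = 8.3e-07). The change at F3 was -1.76 and at F15 -2.02 on the log2 scale. In the met-2;set-25 mutant met-2 changed by -1.95 at P0 in SX1263 and by -1.80 and -1.96 at P0 and F3 in EG6089, and at F3 in SX1263 it was 3.99-fold lower. For set-25 the differences from wild type in SX1263 were smaller. Its level was 278 ± 11.56 CPM in wild-type controls at F3, 125 ± 19.3 CPM in met-2;set-25 (log2 change -1.16) and 186 ± 13.99 CPM in the set-25 mutant, where the change of -0.57 did not pass the test (adjusted p = 0.086). At P0 the change in the set-25 mutant was -0.54 (adjusted p = 0.0076), a call lost without set-25 replicate 3 (adjusted p = 0.064) or wild-type replicate 3 (adjusted p = 0.053). The met-2 mutant, which by its label carries no set-25 mutation, had nearly the same fall in set-25. It fell to 205 ± 14.7 CPM at F3 (log2 change -0.43, adjusted p = 0.042) and by -0.49 at P0 (adjusted p = 0.0011). In SX1263 the falls in the mutants of either gene alone were thus alike in size, and their causes were not tested. In EG6089 met-2;set-25 the falls were larger, to 60.8 ± 4.19 against 166 ± 21.1 CPM at P0 (2.73-fold) and 80.3 ± 9.24 against 239 ± 11.3 CPM at F3 (2.95-fold).

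The first question was how strongly feeding raised small RNAs counted on GFP, and it did so in every genotype. At P0 in SX1263, GFP small RNAs stood at 1817 ± 129 CPM (n = 2) in fed wild-type animals against 79.5 ± 19.5 CPM in their controls, 22.8-fold higher (log2 change 4.51, SE 0.32, adjusted p = 4.2e-07). The rise was 30.6-fold in met-2 (1956 ± 569 against 63.8 ± 8.75 CPM), 22.9-fold in set-25 (1896 ± 446 against 82.8 ± 20.6 CPM) and 19.7-fold in met-2;set-25 (1597 ± 162 against 80.9 ± 32.3 CPM). In EG6089 it was 21.9-fold in wild type (1319 ± 130 against 60.2 ± 8.29 CPM) and 14.1-fold in met-2;set-25 (1016 ± 111.5 against 71.8 ± 25.6 CPM). GFP was the 1 gene that edgeR called in each of these 6 comparisons. A fit with a replicate term called 2 genes in met-2;set-25 of SX1263, where replicate numbers paired the libraries. DESeq2 called 20 genes in met-2, 4 in met-2;set-25, 2 in met-2;set-25 of EG6089 and 27 in wild type of EG6089, and edgeR without the low-count filter called 115 and 84 in the latter 2. No difference in the response between genotypes passed its test at P0. The response in met-2 differed from that in wild type by 0.42 (SE 0.40, adjusted p = 0.38 over 19 tests), that in met-2;set-25 by -0.21, and that of the EG6089 mutant by -0.63 (adjusted p = 0.12 over 19 tests). Over all genes edgeR called 0 genes with a response that differed between genotypes at P0, in SX1263 (114 at an unadjusted p under 0.05, 0 by DESeq2) and in EG6089 (209 at an unadjusted p under 0.05, 0 by DESeq2, 48 without the low-count filter).

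Descendants that never ate the dsRNA still carried raised GFP small RNAs, most of all those of met-2. At F3 GFP small RNAs stood at 638 ± 70.8 CPM in met-2 lines from fed ancestors against 57.1 ± 5.11 CPM in controls, 11.2-fold higher (log2 change 3.48, SE 0.22, adjusted p = 1.7e-08). Wild-type lines were 3.05-fold higher (205 ± 40.3 against 67.2 ± 2.66 CPM, adjusted p = 0.0021) and met-2;set-25 lines 3.72-fold (239 ± 92.6 against 64.1 ± 6.12 CPM, adjusted p = 2.0e-04, a call lost when only these 2 groups were fitted, with a change of 1.86). In set-25, levels were 92.7 ± 15.2 against 69.3 ± 6.98 CPM, a change of 0.42 (SE 0.20) that did not pass the test. By F15 the wild-type lines were at 85.98 ± 3.76 CPM against 81.6 ± 5.71 CPM, a change of 0.08 (SE 0.11), whereas met-2 lines were at 994 ± 69.1 against 56.9 ± 6.28 CPM, 17.5-fold higher (log2 change 4.13, SE 0.12, adjusted p = 3.0e-08). In EG6089 at F3 the rise was 2.82-fold in wild type (238 ± 38.97 against 84.6 ± 6.79 CPM) and 2.67-fold in met-2;set-25 (355 ± 52.2 against 133 ± 9.73 CPM). The EG6089 mutant's controls themselves had more GFP small RNAs than wild-type controls (log2 change 0.65, SE 0.14, adjusted p = 0.0011).

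**Figure D1:**
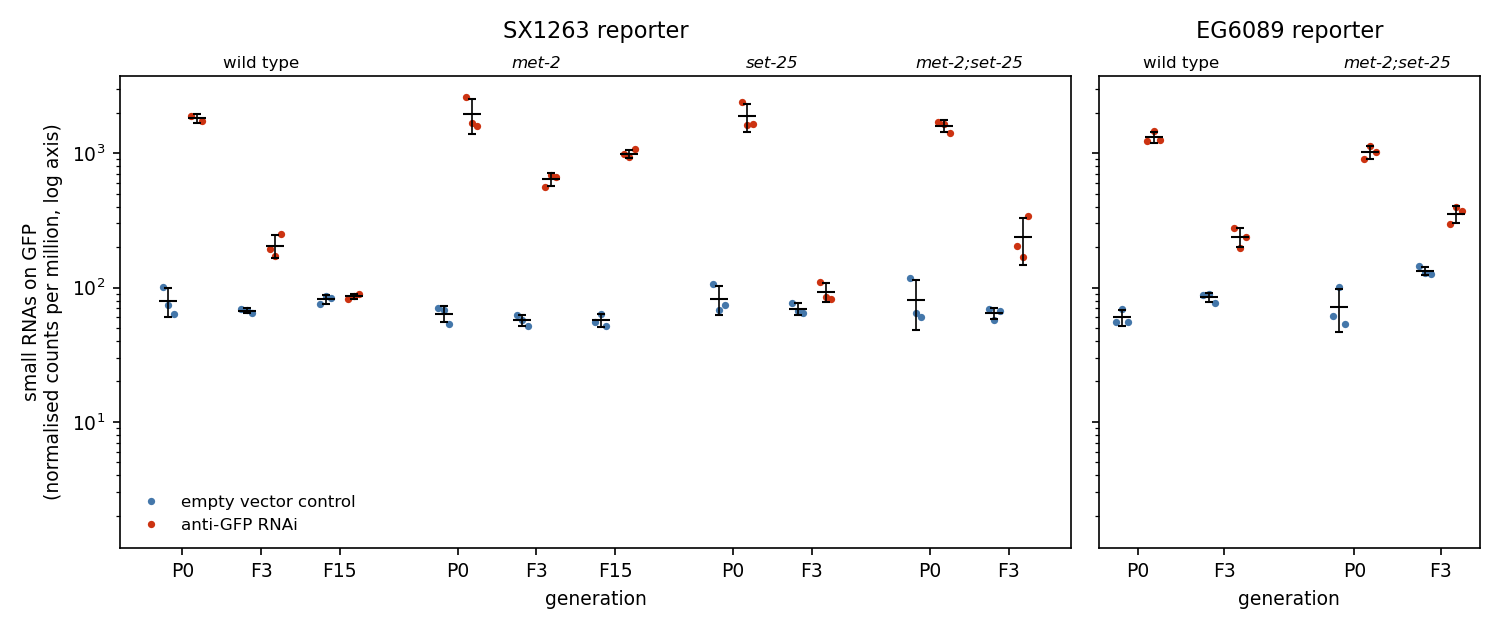
Normalised GFP small RNA level (CPM, log axis) of each library by background, genotype and generation, for control and anti-GFP lines, with group means. Treated met-2 lines stood at 994 CPM at F15 and treated wild-type lines at 85.98 CPM.

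The inherited response differed between genotypes when the differences themselves were tested. The response in met-2 exceeded that in wild type by 1.87 at F3 (SE 0.28, 3.66-fold, adjusted p = 6.3e-06 over 19 tests and 0.026 over all genes) and by 4.05 at F15 (SE 0.16, 16.6-fold, adjusted p = 3.6e-10 over 19 tests). The response in set-25 was below wild type by 2.28-fold at F3 (difference -1.19, SE 0.28, adjusted p = 7.9e-04 over 19 tests), which did not pass over all genes. The met-2;set-25 response at F3 was below that of met-2 (difference -1.59, SE 0.28, adjusted p = 4.2e-05 over 19 tests and 0.076 over all genes, which did not pass) and was not shown to differ from wild type, by 0.29 (SE 0.28) in SX1263 and -0.08 (SE 0.19) in EG6089. GFP was the 1 gene whose response edgeR called different between genotypes over all genes in SX1263 at F3 and at F15, where DESeq2 called 26 and 13 genes. EdgeR called 0 such genes in EG6089 at F3 (443 at an unadjusted p under 0.05, 0 by DESeq2). From P0 to F3 the response fell in each genotype, with differences of -2.87 in wild type, -1.42 in met-2, -4.08 in set-25 and -2.45 in met-2;set-25 on the log2 scale, and of -2.98 and -2.40 in wild type and met-2;set-25 of EG6089. That in met-2 did not pass over all genes (adjusted p = 0.058). From F3 to F15 the difference was -1.53 in wild type (adjusted p = 3.7e-05 over 19 tests and 0.20 over all genes) and 0.60 in met-2 (adjusted p = 0.097 over 19 tests).

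By edgeR few endogenous genes moved with anti-GFP ancestry, and several of their calls were lost without a single library, whereas DESeq2 called 79 genes in met-2 at F3, 69 in met-2 at F15 and 98 in met-2;set-25 at F3. In met-2 at F3, 15 genes were called, 3 higher and 12 lower. Beside GFP the higher ones were unc-13, a synaptic vesicle priming factor (27.8 ± 28.1 against 1.08 ± 0.381 CPM), and the collagen gene sqt-1 (5.88 ± 4.14 against 0.473 ± 0.444 CPM), and both calls were lost without treated replicate 3 (unc-13, adjusted p = 0.10) or 1 (sqt-1, adjusted p = 0.094) or without control replicate 1 or 3 (adjusted p = 0.078 to 0.14). That count of 15 was 2 when only the 2 groups were fitted, 10 without treated replicate 3 and 1.2e+02 without control replicate 2. In met-2 at F15, 10 genes were called, 3 higher and 7 lower, a count that was 3 when only the 2 groups were fitted and 6 with a replicate term. Endogenous unc-119, a neuronal gene, was lower (19.5 ± 7.78 against 104.4 ± 18.9 CPM, log2 change -2.42, adjusted p = 0.0093), as was the Nudix gene ndx-6 (6.37 ± 2.05 against 75.6 ± 42.9 CPM, adjusted p = 0.011, and 0.052 without treated replicate 3). In met-2;set-25 at F3, 11 genes were called, 9 higher and 2 lower, among them R107.2 (log2 change 2.57, 1.71 without treated replicate 1). That count was 0 when only the 2 groups were fitted, 4 without control replicate 2 and 1.1e+02 without treated replicate 3. In EG6089 met-2;set-25 at F3, Y18H1A.11 was called besides GFP (3.88-fold, 30.4 ± 5.56 against 7.79 ± 1.89 CPM). In wild type at F3, edgeR called GFP alone in both backgrounds and DESeq2 called 2 genes in each. A replicate term gave 2 in SX1263. In EG6089 the count was 3 when only the 2 groups were fitted and 2 without the low-count filter. EdgeR called 0 genes in set-25 at F3 (0.979% of 11439 at an unadjusted p under 0.05, 1 by DESeq2) and 0 in wild type at F15 (94 at an unadjusted p under 0.05, 1 by DESeq2). Chance alone would give a share of about 0.05, more than either. These tests were thus strict, and 0 calls do not show that no gene responded. No list kept a call with an estimated correlation in a treatment comparison.

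The CB-unc-119 row moved opposite to GFP in met-2. Treated met-2 lines had 233 ± 14.18 CPM at F3, 2.67-fold below their controls at 623 ± 59.6 CPM (log2 change -1.42, adjusted p = 0.0093), and 33.9 ± 29.2 CPM at F15, 11.8-fold below their controls at 401 ± 91.6 CPM (log2 change -3.56, SE 0.52, adjusted p = 0.038). Leaving out a library moved the F15 change between -3.21 and -4.54. The F15 call was lost without treated replicate 2 or 3 or any control library (adjusted p = 0.051 to 0.11). At P0 the change in met-2 was -0.71 (adjusted p = 0.72). In met-2;set-25 the changes were -0.74 at P0 and -0.97 at F3 (adjusted p = 0.093), and without treated replicate 2 the latter was -1.44 and passed. Wild type changed by -0.10, -0.25 and -0.05 at P0, F3 and F15, and set-25 by -0.19 and -0.13, with no call. The response in met-2 lay below that in wild type by -1.17 at F3 (adjusted p = 0.0034 over 15 tests) and -3.51 at F15 (adjusted p = 0.0028 over 15 tests), and neither passed over all genes (adjusted p = 0.88 and 0.67). Control lines also differed by genotype. Met-2 controls were lower than wild-type controls at F3 (log2 change -1.64, adjusted p = 1.1e-05), and met-2;set-25 controls changed by -1.24.

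**Figure D2:**
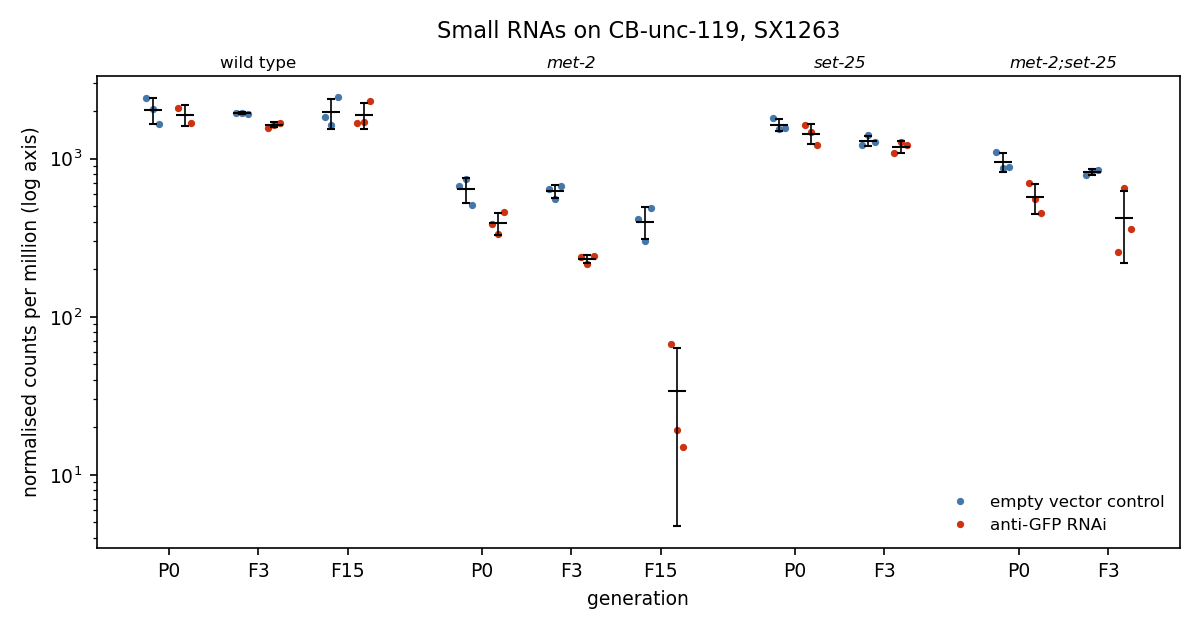
Normalised level of small RNAs on the CB-unc-119 row (CPM, log axis) of each SX1263 library by genotype and generation, for control and anti-GFP lines, with group means. Treated met-2 lines stood at 33.9 CPM at F15, below control met-2 lines at 401 CPM.

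Small RNAs of many genes differed between met-2 and wild type without any treatment. The labels give a single met-2 allele, so other differences between the lines cannot be told apart from loss of the gene. Among 11439 genes tested at F3 in SX1263 controls, 2043 were higher and 1175 lower in met-2. Several genes with no count in wild type gained small RNAs: D2096.6 (IV, 8368344 to 8369235) reached 60.4 ± 38.5 CPM, at least 411-fold higher, asns-1, the gene of an asparagine synthetase (V, 8546174 to 8548880), 55.5 ± 37.7 CPM, at least 378-fold, C40H1.3 29.5 ± 4.80 CPM, at least 200-fold, and the collagen gene col-8 19.8 ± 5.70 CPM, at least 134-fold. Among the genes that lost small RNAs, Y55D5A.1 (III, 2982409 to 2988150) fell 153-fold, from 171 ± 92.6 to 1.10 ± 0.357 CPM, E02H9.9 (III, 2467281 to 2468302) 141-fold, from 178 ± 12.5 to 1.26 ± 0.5003 CPM, and pdfr-1, the gene of a neuropeptide receptor, 68.1-fold, from 199 ± 17.2 to 2.91 ± 0.798 CPM (log2 change -6.09, SE 0.47, adjusted p = 3.7e-08). The F-box gene fbxa-115 was 37.4-fold lower, the C-type lectin gene clec-12 39.9-fold and the cuticlin-like gene cutl-10 41.5-fold lower.

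Gene groups moved in different directions in met-2 at F3. Of the F-box family, 10 of 193 tested members were higher and 97 lower (12 and 105 adjusted over the list alone, camera adjusted p = 2.0e-16, adjusted p = 0.046 with an estimated correlation), such as fbxb-93 (log2 change -2.89) and fbxb-51 (4.29-fold lower). ERGO-1 targets fell, with 1 of 19 higher and 10 lower (2 and 12 adjusted over the list alone, adjusted p = 0.045 with an estimated correlation), among them H09G03.1 (18.9-fold lower, 14.8 ± 1.39 against 279 ± 19.0 CPM), C18D4.6 (4.72-fold) and K02E2.6 (2.43-fold). Cuticle collagens rose, with 27 of 49 higher and 2 lower (27 and 4 adjusted over the list alone, adjusted p = 0.018 with an estimated correlation), as for col-104 (6.71) and col-87 (6.67). Genes on autosome arms fell relative to the rest (443 higher and 681 lower of 4059, 435 and 674 adjusted over the list alone, adjusted p = 0.018 with an estimated correlation). Sperm genes had 26 of 40 higher and 1 lower (28 and 1 adjusted over the list alone, camera adjusted p = 3.8e-06, adjusted p = 0.24 with an estimated correlation). The gene fer-1, needed for sperm to become motile, was 59.0-fold higher (251 ± 61.0 against 4.21 ± 1.02 CPM), and spe-41, a calcium channel gene of sperm, was the member that fell (-3.02). Of intestine genes 15 of 32 were higher and 0 lower (16 and 1 adjusted over the list alone), with pgp-1, a transporter gene, 37.7-fold higher and pept-1, a peptide transporter gene, 4.95-fold higher. The intestine call was lost (adjusted p = 0.24 with an estimated correlation).

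Other groups in met-2 at F3 changed less or in part. Body muscle genes had 10 of 25 higher and 0 lower (11 and 1 adjusted over the list alone, adjusted p = 0.061 with an estimated correlation). Ribosomal protein genes had 1 of 76 higher and 11 lower (1 and 1 adjusted over the list alone), WAGO targets 1 of 16 and 6 (1 and 8), the pals family 2 of 15 and 8 (3 and 10), MATH-BATH genes 4 of 45 and 9 (5 and 10), pseudogenes 34 of 189 and 55 (41 and 60) and the small RNA pathway 3 of 58 and 8 (3 and 8). These 6 calls were lost (adjusted p = 0.24 with an estimated correlation in each). Among them lido-18 fell 3.72-fold, bath-20 3.13-fold and pals-25 6.86-fold. The Piwi gene prg-1 fell from 959 ± 51.6 to 728 ± 63.6 CPM and rde-11, an RNAi factor gene, from 581 ± 48.7 to 363 ± 68.8 CPM. No list call was made for chromatin regulators (0 of 50 higher and 5 lower, 0 and 3 adjusted over the list alone, with lin-15B 2.56-fold lower), oogenesis genes (0 of 78 and 4, 0 and 0), X-chromosome genes (276 of 1150 and 152, 292 and 159), chemoreceptors (15 of 91 and 18, 15 and 18), lectins (12 of 56 and 11, 14 and 11), neuronal genes (10 of 41 and 3, 11 and 5), nuclear hormone receptors (23 of 121 and 20, 25 and 21), histone genes (5 of 32 and 3, 5 and 3), heat shock genes (4 of 14 and 2, 4 and 4), zygotic embryo genes (5 of 21 and 4, 6 and 5) and the reporter list (0 of 5 and 0). Median and mean had opposite signs for heat shock genes (-0.04 and 0.62), histone genes (-0.08 and 0.07), pseudogenes (-0.09 and 0.05) and the small RNA pathway (-0.09 and 0.01). The test pointed down for nuclear hormone receptors (median 0.09, mean 0.30), zygotic embryo genes (0.06 and 0.37) and the reporter list (0.04 and 0.0025), against both.

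Much of the difference between met-2 and wild type was present at P0 and at F15. At P0, 1715 genes were higher and 1257 lower of 12657 tested (2253 and 2353 with a replicate term), and 1214 higher (271 expected by chance) and 805 lower genes (121 expected) were shared with F3 (r = 0.91 across genes, which are not independent replicates). The gene fer-1 was 61.8-fold higher at P0, and Y55D5A.1, E02H9.9 and pdfr-1 were 340-fold, 207-fold and 59.2-fold lower. F-box genes (6 of 220 higher and 108 lower, 7 and 130 adjusted over the list alone) and collagens (29 of 61 and 1, 33 and 2) kept their calls (adjusted p = 0.017 with an estimated correlation in both). At F15, 2035 genes were higher and 1861 lower of 10675 tested (2199 and 2214 with a replicate term), with 1210 higher (309 expected) and 885 lower genes (192 expected) shared with F3 (r = 0.80 across genes). The proton pump subunit gene vha-5 was 497-fold higher (414 ± 161 against 0.831 ± 0.369 CPM), rga-6 220-fold and the integrin gene pat-2 91.0-fold. Y55D5A.1 was 861-fold lower, arrd-15 92.3-fold and sdc-1, a dosage compensation gene on X, 9.23-fold (21.3 ± 1.39 against 197 ± 20.2 CPM). Sperm genes had 41 of 48 higher and 1 lower (42 and 1 adjusted over the list alone, adjusted p = 0.42 with an estimated correlation), with spe-8 6.61-fold and fog-3 8.56-fold higher. F-box genes had 9 of 160 higher and 98 lower (11 and 110 adjusted over the list alone, adjusted p = 0.30 with an estimated correlation). X-linked genes took 3.87 ± 0.40% of gene counts in met-2 at F15 and 6.98 ± 0.51% in wild type (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The test for a met-2 effect that differed between F15 and F3 called 480 genes, 46 with a higher and 434 with a lower effect at F15, with ttn-1, saeg-1, ZK430.5, F16B4.5, K03H6.5 and Y34B4A.2 at the smallest p. A fit of the 12 libraries concerned alone called 139 genes, a count that 9 of 100 labelings reached, the real one included. The labelings moved generation labels within each genotype, so a change with generation in either genotype can raise their counts too. Leaving out a library moved the count of 480 between 284 (without met-2 F3 control replicate 1) and 629 (without met-2 F3 control replicate 2).

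**Figure D3:**
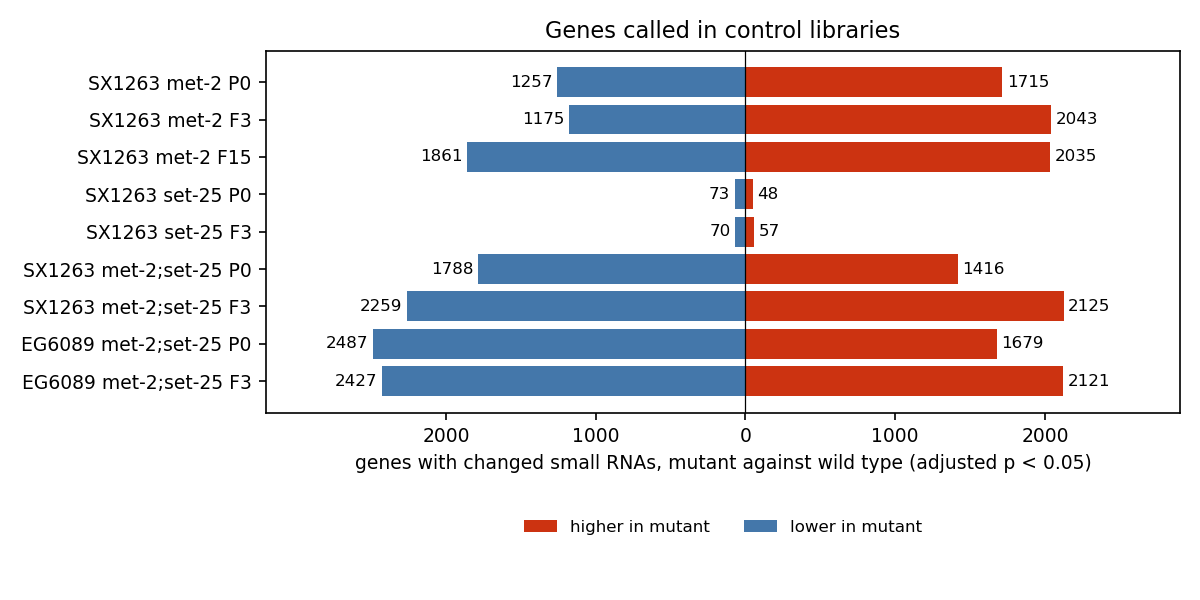
Number of genes called higher and lower in control libraries of each mutant against wild type (adjusted p under 0.05), by background and generation. The set-25 mutant had 127 calls at F3, against 3218 for met-2.

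The set-25 mutant differed from wild type in far fewer genes, with the same limit of a single allele. At F3, 57 genes were higher and 70 lower, and at P0 48 and 73 (114 and 155 with a replicate term, where replicate numbers paired the libraries). The octopamine receptor gene ser-3 (I, 6820517 to 6823093) fell 40.3-fold at F3, from 313 ± 37.3 to 7.77 ± 1.21 CPM, and 44.2-fold at P0. The serotonin receptor gene ser-5 fell 14.8-fold (142 ± 15.9 to 9.58 ± 2.31 CPM) at F3 and 31.04-fold at P0, F31E9.6 17.4-fold at F3, and the muscle myosin gene unc-54 14.1-fold (15.4 ± 0.788 to 1.07 ± 0.192 CPM). The lysosomal regulator gene hlh-30 fell 7.62-fold. Higher were cutl-14 at P0 (15.1-fold, 119.2 ± 37.8 against 7.85 ± 1.10 CPM) and Y116F11B.9 at F3 (7.27-fold, 39.8 ± 10.03 against 5.49 ± 0.606 CPM). ERGO-1 targets at F3 had 0 of 19 higher and 1 lower (0 and 7 adjusted over the list alone, camera adjusted p = 1.1e-08, adjusted p = 0.043 with an estimated correlation), with C18D4.6 4.90-fold lower. F-box genes had 0 of 193 higher and 7 lower at F3 (1 and 12 adjusted over the list alone, adjusted p = 0.52 with an estimated correlation). The P0 and F3 sets shared 19 higher and 39 lower genes (0.23 and 0.45 expected). Without 1 library the F3 count was 46 to 70, and the P0 count of 121 was 62 to 90. Control and treated libraries together gave 505 calls at F3 and 418 at P0. A fit of the 2 compared groups alone gave 516 at F3.

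The met-2;set-25 mutant of SX1263 differed from wild type at many genes in both directions, and its list calls at F3 were lost with an estimated correlation. At F3, 2125 genes were higher and 2259 lower, and at P0 1416 and 1788 (2093 and 3003 with a replicate term, where replicate numbers paired the libraries). The F3 split turned under RLE (2276 higher and 2163 lower) and by DESeq2 (2376 and 2230). T28B8.1 was 153-fold higher (591 ± 196 against 3.95 ± 2.05 CPM), the collagen gene col-87 111-fold, T23F4.2 108-fold and the lectin gene clec-204 57.2-fold. E02H9.9 was 301-fold lower (0.543 ± 0.228 against 178 ± 12.5 CPM), Y55D5A.1 146-fold and the nuclear receptor gene nhr-236 93.4-fold. H09G03.1 fell 18.7-fold and F52D2.12 21.4-fold, and the germline Notch receptor gene glp-1 1.92-fold. Of X-chromosome genes, 453 of 1150 were higher and 69 lower at F3 (467 and 73 adjusted over the list alone, camera adjusted p = 2.7e-10, adjusted p = 0.23 with an estimated correlation), and 331 of 1306 and 50 at P0 (346 and 53 adjusted over the list alone, adjusted p = 0.028 with an estimated correlation). Their share of all counts was 7.26 ± 0.47% in the mutant and 7.24 ± 0.20% in wild type at F3. F-box genes had 20 of 193 higher and 99 lower at F3 (20 and 102 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation) and ERGO-1 targets 1 of 19 and 12 (1 and 13 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation). Of intestine genes 18 of 32 were higher and 1 lower (19 and 1 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation), with pept-1 9.85-fold and the yolk gene vit-5 4.39-fold higher. Ribosomal protein genes had 2 of 76 higher and 28 lower (2 and 28 adjusted over the list alone, adjusted p = 0.77 with an estimated correlation), with rps-21 4.25-fold lower. Sperm genes (9 of 40 higher and 3 lower, adjusted p = 0.15) and collagens (7 of 49 and 5, adjusted p = 0.73) were not called as lists. Control replicate 2 of this group at F3 stood apart, with 3583283 gene counts.

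The met-2;set-25 mutant of EG6089 gave a second reading of the same genotype. At F3, 2121 genes were higher and 2427 lower of 8943 tested, and at P0 1679 and 2487. The T-box gene mab-9 reached 140 ± 48.5 CPM from no counts, at least 570-fold higher, B0303.14 rose 715-fold (1527 ± 346 against 1.95 ± 0.814 CPM), F38E11.6 672-fold (295 ± 2.54 against 0.410 ± 0.0853 CPM) and the cytochrome gene cyp-33E1 429-fold. T05B9.2 fell from 31.8 ± 2.81 CPM to no counts, at least 111.5-fold, E02H9.9 259-fold, the secreted anosmin gene kal-1 48.02-fold and math-44 59.0-fold. F-box genes had 13 of 138 higher and 88 lower (13 and 88 adjusted over the list alone, camera adjusted p = 3.0e-08, adjusted p = 0.052 with an estimated correlation). All 9 tested pals genes were lower (9 adjusted over the list alone, adjusted p = 0.085 with an estimated correlation), with pals-25 5.45-fold. Ribosomal protein genes had 0 of 73 higher and 35 lower (0 and 35 adjusted over the list alone, adjusted p = 0.052 with an estimated correlation), with rps-21 10.1-fold lower, and ERGO-1 targets 0 of 19 and 12 (0 and 12 adjusted over the list alone, adjusted p = 0.071 with an estimated correlation). Intestine genes had 11 of 21 higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.052 with an estimated correlation), with the gut esterase gene ges-1 15.8-fold higher, and neuronal genes 13 of 28 and 6 (13 and 6 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation), with unc-25, needed to make GABA, 90.1-fold higher. X-chromosome genes had 164 of 817 higher and 191 lower (adjusted p = 0.99) and took 5.74 ± 0.47% of counts, against 7.91 ± 0.16% in wild type. At P0 the split of the 4166 calls depended on scaling, with 1987 higher and 2038 lower under RLE and 2142 and 2079 by DESeq2, and the median of all genes was -0.11 under TMM and 0.06 under RLE.

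Both backgrounds shared much of the difference between this genotype and wild type. The labels give the same alleles in both, so variants carried along with them cannot be told apart from loss of the genes. At F3, 1006 higher (371 expected) and 1587 lower genes (549 expected) were common to met-2;set-25 of SX1263 and EG6089 (r = 0.74 across genes), and at P0 758 (192 expected) and 1299 (430 expected). The gene mihp-1 changed by 4.44 and 4.99, H09G03.1 by -4.23 and -4.14, E02H9.9 by -8.24 and -8.02 and fbxa-115 by -4.05 and -3.87. Between mutants of SX1263 at F3, taking control libraries for the met-2 effect and treated libraries for the set-25 effect so that no library was shared, 29 higher (9.5 expected) and 31 lower genes (5.8 expected) were common and 16 moved in opposite directions (r = 0.28 across genes). A run of 14 neighbouring genes on chromosome II (1645410 to 1688913) was called lower throughout in met-2;set-25 of SX1263 at F3. It was picked as the longest such run in that comparison, so those 14 calls follow from the choice. Of its genes 12 were called lower in met-2 and 1 in set-25, against the same wild-type libraries. In EG6089 met-2;set-25 the run had 11 of 12 tested genes called lower. Its F-box gene fbxb-26 was 3.40-fold lower in met-2 (21.2 ± 8.48 against 72.0 ± 4.92 CPM). Its gene btb-12 was 4.34-fold lower in met-2, 8.62-fold in met-2;set-25 and 14.8-fold in EG6089 met-2;set-25.

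**Figure D4:**
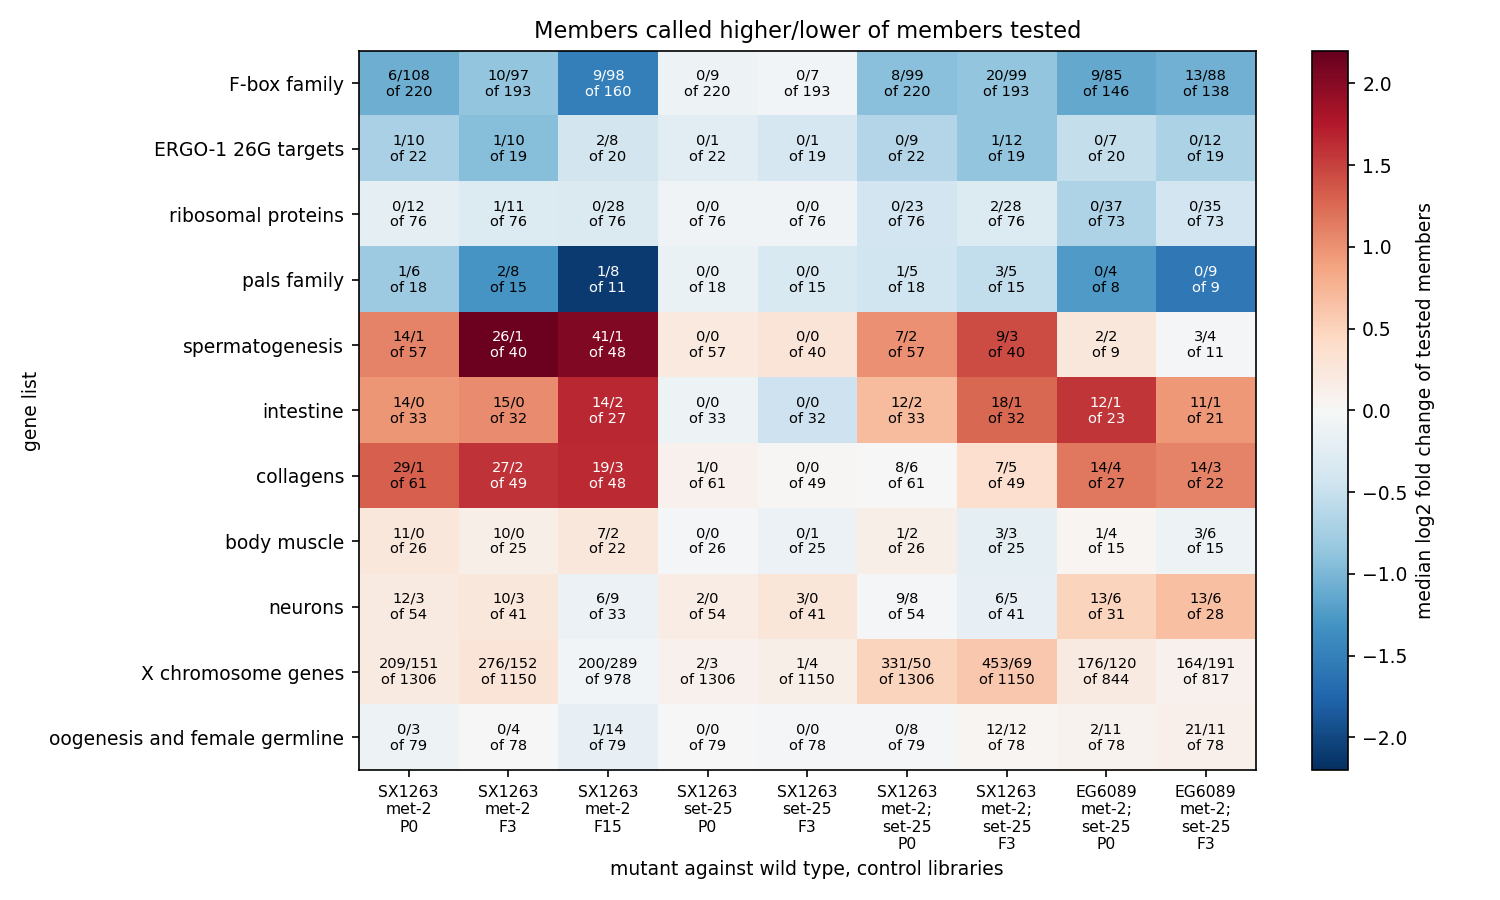
Median log2 change of the tested members of each gene list in control libraries of each mutant against wild type. F-box genes had a median of -0.87 in met-2 at F3 and -0.05 in set-25 at F3.

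**Figure D5:**
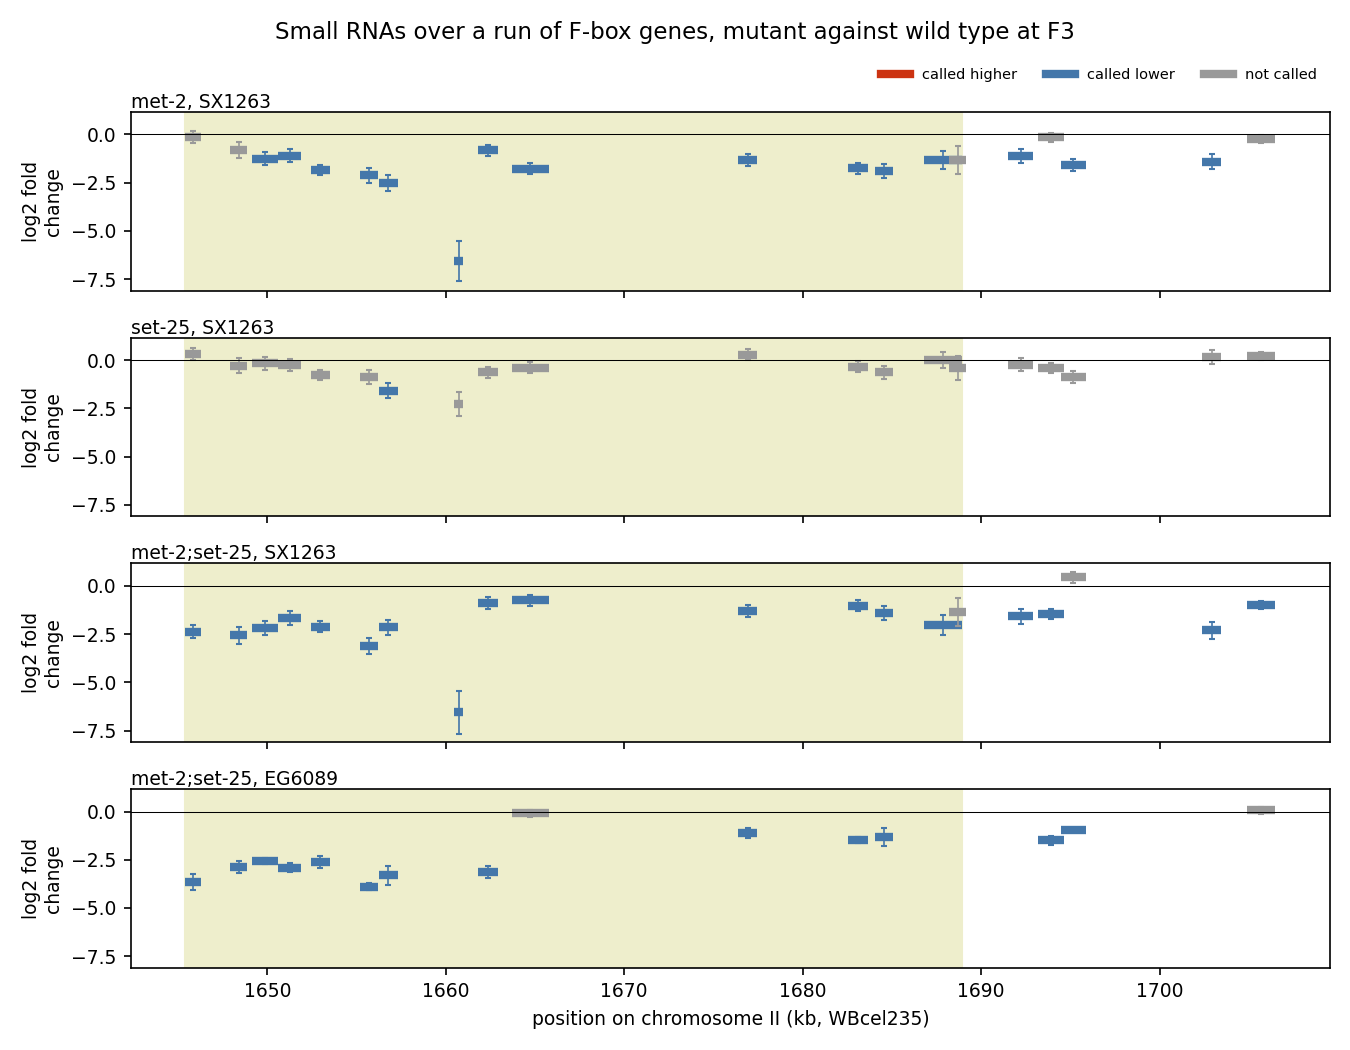
Genes of chromosome II around 1645410 to 1688913 drawn to scale, with the log2 change of each tested gene against wild type at F3 in 3 mutants of SX1263 and in EG6089 met-2;set-25. All 14 genes of the run were lower in met-2;set-25 of SX1263, the comparison by which the run was picked.

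Direct comparison of met-2 with set-25 asked where the mutants differ from each other. At F3, 1722 genes were higher and 1136 lower in met-2 than in set-25, and at P0 1397 and 1160 (1868 and 1964 with a replicate term). F22B5.4 (20.5 ± 13.7 CPM) and pqn-16 (20.3 ± 9.70 CPM) had no counts in set-25 at F3, at least 170-fold and at least 169-fold below met-2, and at P0 the transporter gene slc-17.8 was 695-fold higher in met-2. Y55D5A.1 was 288-fold lower in met-2 than in set-25 at F3 and 463-fold at P0, and its neighbour Y55D5A.4 72.4-fold and 65.3-fold lower.

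Between generations of wild-type controls the differences were smaller, and generation went with food between P0 and F3. In SX1263 from P0 to F3, 29 genes were higher and 86 lower, with the yolk gene vit-2 2.98-fold higher (11.3 ± 0.675 against 3.76 ± 0.917 CPM) and F15B9.10 2.34-fold. Under RLE the split was 44 and 79, and leaving out a library moved the count between 9 (without wild-type F3 replicate 2) and 123. From F3 to F15, 36 genes were higher and 22 lower, with the gene row of the ERGO-1 target C40A11.10, whose symbol in the annotation is cel-mir-8199, 4.496-fold lower (38.3 ± 3.17 against 172 ± 8.47 CPM), a call lost without any library but wild-type F15 replicate 1 (adjusted p = 0.077 to 0.12). This count was 1 without wild-type F15 replicate 2 and 122 without replicate 1. In EG6089 from P0 to F3, 454 genes were higher and 335 lower, among them ucr-2.2 (7.68-fold higher), pept-3 (5.31-fold) and the ERGO-1 target F52D2.6 (5.63-fold, 330 ± 70.3 against 58.7 ± 8.88 CPM), whereas mltn-8 was 4.64-fold lower. This split turned under RLE (291 higher and 490 lower) and by DESeq2 (451 and 670), with a median of all genes of -0.0038 under TMM and -0.11 under RLE. Leaving out a library moved the EG6089 count between 96 (without P0 replicate 2) and 1287 (without P0 replicate 1).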

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

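The pairwise tests of the GFP and CB-unc-119 rows, all 3 tests of the CB-unc-119 pattern, the oogenesis test, the 2 further sums of sperm genes and the test of F-box members by level in EG6089 were chosen after the result was seen. The GFP and CB-unc-119 results and the counts of differing effects drew attention because an effect differed between genotypes or generations in a test of the difference itself. The sperm and F-box results are plain list results of a mutant against wild type, with no such test behind them.

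GFP small RNAs responded to anti-GFP ancestry by more in met-2 than in wild type, by 1.87 at F3 and 4.05 at F15 on the log2 scale. The response was smaller in set-25 than in wild type at F3 (-1.19) and smaller in met-2;set-25 than in met-2 (-1.59), and neither passed over all genes. From P0 to F3 it changed by -2.87 in wild type, -1.42 in met-2, -4.08 in set-25 and -2.45 in met-2;set-25 of SX1263, and by -2.98 and -2.40 in wild type and met-2;set-25 of EG6089. From F3 to F15 it changed by -1.53 in wild type. Over all genes, the response differed between genotypes for 1 gene at F3 and for 1 at F15 in SX1263, which was GFP in both. Between P0 and F3 the food changed with the generation, which leaves the cause of the fall open.

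The met-2 effect in control libraries differed between F15 and F3 for 480 genes. Relabelling was run in a fit of the 12 libraries concerned alone, which called 139 genes. Of 100 labelings, the real one included, 9 gave as many, and the highest other gave 2138. Generation labels were moved within each genotype, so a labeling can carry a generation effect common to both genotypes into the test. The labelings thus cannot say how often chance alone gives such a count, and chance was not excluded. Counts as high as 2138 may come from generation or from another structure of the samples.

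Small RNAs of the CB-unc-119 row were lower in treated met-2 lines, and the response lay below that in wild type by -1.17 at F3 and -3.51 at F15, with a change from F3 to F15 of -2.18. The first 2 did not pass over all genes (adjusted p = 0.88 and 0.67). A few genes taking most of the counts would lower the median of all genes in counts scaled to library size alone, which changed by -0.029 at F15. Reads moving between this row and endogenous unc-119 would leave their sum in place, but the sum was lower too (log2 ratio -3.24, 53.4 ± 24.6 against 505 ± 92.5 CPM, n = 3 and 3, exact permutation p = 0.1, the smallest possible). The row was lower in 5 of 5 comparisons of met-2 and met-2;set-25 lines, which may reflect the treatment or lines that drifted apart after a common start, and the number of lines cannot settle this. By less and without a call, it was also lower in wild type (-0.10, -0.25 and -0.05 at P0, F3 and F15). In set-25 the changes were -0.19 at P0 and -0.13 at F3. Direction alone therefore does not set met-2 and met-2;set-25 apart. A biological explanation, that small RNAs on GFP in met-2 take the place of others on the same transgene, remains an untested hypothesis, and that this row belongs to the GFP transgene is itself unknown.

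Sperm genes were higher in met-2 at F3 with 26 of 40 called, but the list call was lost with an estimated correlation (adjusted p = 0.24). Reads shared between paralogs would move counts among members, but the summed list was higher by 1.09 on the log2 scale (564 ± 71.4 against 266 ± 11.3 CPM, 2.12-fold). The gene fer-1 alone made 82.6% of that rise, and without it the sum differed by 0.26, which decides nothing. The summed multigene families of the list, where shared reads are most likely, were higher by 2.14 (87.9 ± 25.3 against 19.9 ± 3.11 CPM), so that moves of reads among those members are not the cause there. The 23 tested members of multigene families had 17 higher with a median of 2.16, and the 17 others 9 higher with a median of 2.19. All genes of the list outside these families summed to 477 ± 74.3 against 246 ± 13.2 CPM. Since fer-1, which is among them, alone gained 247 CPM, the rest of them did not rise in sum. A shift of the samples away from oocyte-bearing animals would lower oogenesis genes, whose median change was -0.0010. Scaling centres most genes on 0, however, and could hide a shift common to many of them. A small share of males could also add sperm RNA without moving that median. The median therefore leaves such a shift open. That loss of met-2 changes small RNAs of sperm genes is a hypothesis that these tests leave standing.

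F-box genes were lower in met-2;set-25 of both backgrounds at F3, but the list call was lost with an estimated correlation in SX1263 (adjusted p = 0.23) and in EG6089 (adjusted p = 0.052). Other arm genes did not fall as far: the family median of -0.88 in SX1263 lay at percentile 0 among 10000 lists of them matched on level. Medians of those lists centred on -0.05 with a lowest of -0.33. The lists drew genes singly, whereas family members can lie side by side and share reads. The percentile therefore cannot exclude location as a cause. Location may still contribute, since the 23 members in autosome centres had a median of only -0.14, and the 14 in EG6089 -0.17 against -1.06 for that family. The 97 members with the higher levels had a median of -0.68 in SX1263, so that members near the floor are not the whole cause there, but the corresponding median in EG6089 was -0.34, which leaves it open. Reads shared between family members may contribute, since the summed family changed by only -0.39 in SX1263 and -0.43 in EG6089, between the bounds set for and against that cause. The histone methyltransferases as the biological cause, through the chromatin of these genes, remain an open hypothesis.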

How the results depend on the processing

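The pairwise reporter tests and the 12-library fit were chosen after the data were seen, and all alternatives here were planned. The direction and call of GFP in each of the 14 treatment comparisons held in 83 of 84 alternatives and in 83 of 83 fits without 1 library. The exception was met-2;set-25 at F3 in SX1263, whose change of 1.89 was 1.86 and not called when only its own 2 groups were fitted. Without 1 library the GFP change ran from 4.38 to 4.73 in wild type at P0, 3.42 to 3.57 in met-2 at F3, 4.07 to 4.23 in met-2 at F15 and 1.52 to 2.06 in met-2;set-25 at F3. Among named genes, called or not, 7394 alternatives left that status unchanged, 106 lost a call and 26 gained one, and fits without 1 library left 6290 unchanged, lost 374 calls (over 110 results) and gained 6. Of the alternatives 2 reversed: GFP in met-2 against wild type was 0.96 at F3 and 1.55 at F15 with control and treated libraries together, since treated met-2 libraries carry the inherited signal. Among lists, called or not, 989 alternatives left that status unchanged, 110 lost a call and 5 gained one. RLE scaling and restriction to protein-coding genes and pseudogenes moved no total of calls by more than 1.5 times, but RLE moved the higher calls from P0 to F3 from 454 to 291 in EG6089 and from 29 to 44 in SX1263. Depth limits genes near the floor, and the simulated 2-fold changes were recovered in under 50% in SX1263.

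Counts moved as follows, and the cause was not tested. DESeq2 gave 139 in place of 58 from F3 to F15 and 245 in place of 115 from P0 to F3 in SX1263. For treatment it gave 69 in met-2 at F15, 79 at F3 and 20 at P0, 98 in met-2;set-25 at F3 and 4 at P0, 1 in set-25 at F3, 1 and 2 in wild type at F15 and F3, and in EG6089 5 and 2 in met-2;set-25 at F3 and P0 and 2 and 27 in wild type. It gave 13 and 26 genes with a differing response at F15 and F3, and 278 and 216 for set-25 at F3 and P0. Control and treated libraries together, a larger sample, gave 4616 for met-2 and 5318 for met-2;set-25 at P0, and 505 and 418 for set-25 at F3 and P0. No low-count filter, with more genes tested, gave 19 from F3 to F15, and in EG6089 6 and 115 for treatment of met-2;set-25 at F3 and P0, 2 and 84 for wild type, and 48 in place of 0 for the differing response at P0. Fitting only the compared groups took the spread from fewer libraries and no longer shared it with the other groups. It gave 430 from F3 to F15, and 3, 2 and 0 for treatment of met-2 at F15 and F3 and met-2;set-25 at F3. For treatment in EG6089 at F3 it gave 1 in met-2;set-25 and 3 in wild type. It also gave 1637 for met-2 against set-25 at P0, 1952 for met-2 at P0 and 516 for set-25 at F3.

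Replicate numbers were tested as pairs in 28 comparisons, where the correlation of paired libraries ran from -0.28 to 0.70, and pairing held in 9. A replicate term gave 99 from F3 to F15, 200 and 1298 from P0 to F3 in SX1263 and EG6089, 6 for treatment of met-2 at F15, 18 and 2 of met-2;set-25 at F3 and P0, 2 of wild type at F3, 4606 for met-2, 5096 for met-2;set-25 and 269 for set-25 at P0. Pairing held in the latter 2 and in the treatment of met-2;set-25 at P0.

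Leaving out 1 library gave 1 to 122 genes from F3 to F15, 9 to 123 from P0 to F3 in SX1263 and 96 to 1287 in EG6089. For treatment it gave 10 to 1.2e+02, 1 to 14 and 7 to 15 in met-2 at F3, P0 and F15, 4 to 1.1e+02 and 1 to 3 in met-2;set-25 at F3 and P0, 2 to 12 and 1 to 13 in met-2;set-25 and 1 to 24 in wild type at P0 of EG6089. Differing responses ran from 0 to 1 at P0, 1 to 9 at F3 and 1 to 6 at F15 in SX1263, 0 to 1 in EG6089 at F3, and 284 to 629 for met-2 by generation. For set-25 the counts were 46 to 70 at F3 and 62 to 90 at P0. The counts for met-2 and met-2;set-25 stayed within 1.5 times, at 2514 to 2899 for met-2 at F3, 2986 to 3801 at F15, 3538 to 4400 for met-2;set-25 at F3 and 4013 to 4401 in EG6089 at F3.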

Other observations

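The tests of neighbouring genes were chosen after the values were seen, and the counts over other splits of the samples were planned.

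Genes that gained small RNAs in met-2 often lay side by side. On chromosome V, asns-1, stdh-4 and the acetylcholine receptor gene acr-15 lie within 8546174 to 8555383, next to the transporter gene slc-17.8 (8539727 to 8545581). None of asns-1 at F3 or stdh-4 and acr-15 at P0 had a count in wild type, and all had small RNAs in met-2: asns-1 55.5 ± 37.7 CPM at F3, stdh-4 14.4 ± 7.27 CPM and acr-15 15 ± 7.46 CPM at P0, at least 378-fold, at least 173-fold and at least 180-fold higher. The gene slc-17.8 stood at 147 ± 49.1 CPM in met-2 at P0. The longest run of neighbours called higher in met-2 at F3 held 9 genes (V, 12891523 to 12941847). The longest run called lower held 12 genes (II, 1649138 to 1688913), of which 7 were F-box family members, and in met-2;set-25 of SX1263 it reached 14 genes.

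A hypothesis from these runs is that the effect of met-2 acts on stretches of chromosome rather than gene by gene. Genes were relabelled within each chromosome 10000 times, with pairs of 1 gene family left out. Families were told by symbol alone, so relatives named otherwise stayed in. The relabelling did not keep genes on their chromosome arm or at their level. Arm genes fell relative to the rest in met-2 at F3, so some excess of pairs can arise without action on stretches. In met-2 at F3, 570 neighbouring pairs were both higher, against a mean of 323 and a highest of 382 over relabellings, and 235 pairs were both lower, against 97.4 and 140 (permutation p = 1e-04 in both, the smallest they can give, one-sided). With all families the counts were 590 and 280. In met-2;set-25 of SX1263 there were 495 higher pairs against a mean of 395, and 485 lower pairs against 390.5. In set-25 there were 2 higher pairs against a mean of 0.23 and a highest of 4 (permutation p = 0.02). The 6 lower pairs of set-25 stood against 0.45 and 5 (permutation p = 1e-04). Pairs of 1 family were again left out. Neighbours were tested protein-coding genes in order, so genes that were not tested may lie between them. Pairs on the same strand were not set apart from others. Runs kept genes whose annotated spans overlap, but such genes were not counted as pairs. Transcripts that overlap beyond these spans and unstated strand use could still place counts on 2 neighbours at a time, and this was not tested.

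Other groupings of the same libraries were tried for each count of called genes. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For anti-GFP against control at P0, the real split gave 1 gene in each comparison, and the splits with as many numbered 9 of 10 in met-2 (highest other 150), 1 in set-25 (0), 5 in met-2;set-25 (3), 1 in wild type of EG6089 (0) and 5 in its met-2;set-25 (195). Wild type of SX1263 at P0, with 2 treated libraries, was not split. At F3 they numbered 1 in wild type (real 1, highest other 0), 7 in met-2 (15, 205), 3 in met-2;set-25 (11, 624), 3 in wild type of EG6089 (1, 2) and 4 in its met-2;set-25 (2, 36). At F15 they numbered 2 in met-2 (10, 14). The real count was 0 in set-25 at F3 and in wild type at F15, which any split reaches, so splits test nothing there. The splits with 150, 205, 624, 195 and 36 genes call many times the real count and point to a structure of the samples other than the treatment. Replicate numbers pair the libraries in met-2 at P0 and F3 and in met-2;set-25 at P0 in SX1263 and EG6089, where other splits that part all 3 pairs as the real one does gave at most 2, 11, 0 and 0 genes, and those that part 1 pair gave up to 150, 205, 3 and 195.

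In every comparison of mutants in control libraries the real split alone reached its count, 1 of 10 splits. The highest other split gave 0 genes, or 1 for met-2 against wild type at F3, against real counts from 121 to 4548. The same held between generations, with 115, 58 and 789 genes in the real splits and 0, 3 and 0 in the highest others. For tests of whether the response differed between genotypes, 100 labelings were used. At F3 in SX1263, 74 gave as many as the real 1 gene (highest other 1054), and at F15 42 gave as many as 1 gene (3). Chance was thus not excluded for these counts, which is apart from the test of GFP itself. Treatment labels were moved within each genotype and generation, so a response common to the genotypes can also add to the counts of labelings. In EG6089 the real count was 0 at P0 and F3, which every labeling reaches, so the labelings test nothing there.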
